A study of Saccharomyces cerevisiae and Saccharomyces cerevisiae
Drosophila melanogaster with 20 samples.

How the data were processed

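The series comprised 20 libraries of native MNase chromatin immunoprecipitation from Saccharomyces cerevisiae, 1 per group: Mot1 IP and input in W1588-4C (4 libraries), Mot1 IP and input in the W303 anchor-away strain with and without rapamycin (8 libraries) and TBP IP and input in YPH499 with WT Mot1 or mot1-42 (8 libraries), each at 2.5 and 10 min of MNase. Reads were aligned with Novoalign 2.08.01 to sacCer3 per the submitters' processing notes. The deposited files list the chromosome, start and end of each aligned fragment, not normalised, and these coordinates were used as deposited, with repeats of a fragment kept. Whether multiply mapping or low quality pairs had been removed is not stated. For the 4 libraries without rapamycin, the authors gave fragments assigned to yeast and fragments assigned to Drosophila melanogaster apart, and only the yeast fragments entered the comparisons. The rule that split yeast from fly fragments is not stated.

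Fragments were counted by their midpoint with numpy 2.4.6 and pandas 2.3.3 under Python 3.11.15, and tests used scipy 1.17.1 and plots matplotlib 3.10.9. The gene annotation was that of the R64 assembly (sacCer3). Promoters were the 300 bp upstream of the annotated start codon of nuclear protein-coding genes. Of 6002 genes, 237 were left out because the window overlapped another coding gene by more than 50%, and 186 more because it lay within 250 bp of a tRNA or other RNA polymerase III gene, leaving 5579, of which 1675 shared the window with a divergent gene. Background windows were 456 intergenic regions between convergent genes. Fragments of 100 bp or less were scaled to the nuclear fragments of that length in the library (CPM), with a pseudocount of 1 CPM in log2 ratios.

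A promoter was bound when IP over input was at least 2-fold at both times with at least 20 IP fragments at each. Between conditions, a promoter was called higher or lower when the log2 ratio of IP libraries was at least 1 in size, with the same sign, at both times and the exact conditional binomial 95% interval of the ratio excluded 1 at both. The mot1-42 comparison ran over promoters TBP-bound in either strain, and the rapamycin comparison over promoters Mot1-bound in W1588-4C. Shares have exact Clopper-Pearson 95% intervals, and medians have order-statistic 95% intervals over promoters. No test between conditions was made, because each group had 1 library and digestion times are not replicates. Summit positions were the maxima of midpoint density smoothed over 21 bp, from 500 bp upstream to 100 bp downstream of the start codon. On simulated data, 50 promoters were changed per direction and size. The rule recovered 49 to 50 of those changed 4-fold and 48 to 50 of those changed 3-fold. It called 0 of 4397 unchanged promoters in the mot1-42 comparison and 0 of 89 in the rapamycin comparison. These counts cover only part of the 5579 promoters, a small part for rapamycin. In the Mot1 IP without rapamycin at 2.5 min, the Mot1-bound promoters together held 1693 fragments of 100 bp or less. Recovery was not given by fragment count, so it is not shown for promoters with few fragments. The simulation held counting error only, so it does not measure false calls in the data, where 21 of 456 background windows met the rule for higher TBP and 22 for lower.

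Before the data were examined, 17 gene lists were fixed: cytosolic and mitochondrial ribosomal proteins, ribosome biogenesis, glycolysis and fermentation, heat shock and chaperone, general stress, amino acid biosynthesis, hexose transporters, galactose, phosphate, histones, mating, seripauperins, the COS family, proteasome, oxidative phosphorylation, and 3 genes linked to Mot1 in the literature. Each list was described by its median and by that median's percentile among 10000 random lists of the same size matched in 20 bins of mean IP CPM (seed 1), which describes these libraries and is not a test. For IP over input the matched density is the numerator of the ratio, so there the percentile mainly reflects the input. Named promoters were chosen by a rule fixed at the same time: per comparison the 12 with the largest ratio in each direction, ranked by the smaller of the ratios at both times, up to 4 members of each list with the mean ratio largest in size, and URA1, BNA1, INO1, MOT1 and SPT15. Windows for RNA genes spanned the gene and 100 bp on either side, and gene body windows were the central 300 bp of genes over 1500 bp.

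Alternatives changed 1 choice at a time: fragment length (75 bp or less, all lengths), window (200 bp upstream, 400 bp upstream to 100 bp downstream), repeats counted once, each digestion time alone, promoters without a divergent partner, a minimum of 100 fragments, 1.5-fold and 3-fold thresholds, a pseudocount of 5 CPM, division by the input ratio (with a normal approximation for the interval), scaling to background windows and smoothing over 51 bp. Scaling without the ribosomal DNA, and all alternatives for list medians, were added after the data were seen, as were the shuffles of summit pairs (10000) and of Mot1 ranks within strata (1000). No genome sequence was used here, so TATA boxes and poly(dA:dT) tracts, named in the study's question, were not analysed here, and neither were centromeres.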

Results

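The 20 libraries held paired-end fragments from native chromatin of budding yeast that was digested with micrococcal nuclease (MNase) for 2.5 or 10 min, taken either before immunoprecipitation (input) or after it (IP). Mot1, an ATPase that removes the TATA-binding protein (TBP) from DNA, was precipitated through a FLAG tag from strain W1588-4C (4 libraries) and from a W303 anchor-away strain (8 libraries). In the anchor-away strain, rapamycin tethers TBP fused to FRB to a ribosomal protein that leaves the nucleus, and cells were treated with 1 mcg/ml for 60 min or left untreated. TBP was precipitated through a MYC tag from YPH499 cells (8 libraries) whose chromosomal MOT1 gene was deleted and which carried a plasmid with either wild-type (WT) MOT1 or the temperature-sensitive allele mot1-42, both after 45 min at 35 °C. Each of the 20 groups had 1 library, so no check against replicates was possible, no test between conditions was made, and "higher" and "lower" refer to a fixed rule of size met at both digestion times. Intervals are 95% intervals for counting error, or over promoters for medians, and cover no other source of error.

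Yeast fragments per library ranged from 2411748 (Mot1 IP, W303 without rapamycin, 2.5 min) to 28640945 (Mot1 input, W1588-4C, 10 min). Promoter values rested on nuclear fragments of 100 bp or less, the length class protected by proteins smaller than a nucleosome, which numbered 138079 to 9500898 per library, the smallest again in the Mot1 IP without rapamycin at 2.5 min. In the Mot1 IP of W1588-4C at 10 min 35.4% of the fragments were in this class, against 14.9% in the input, and the median length was 128 bp against 158 bp.

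**Figure D1:**
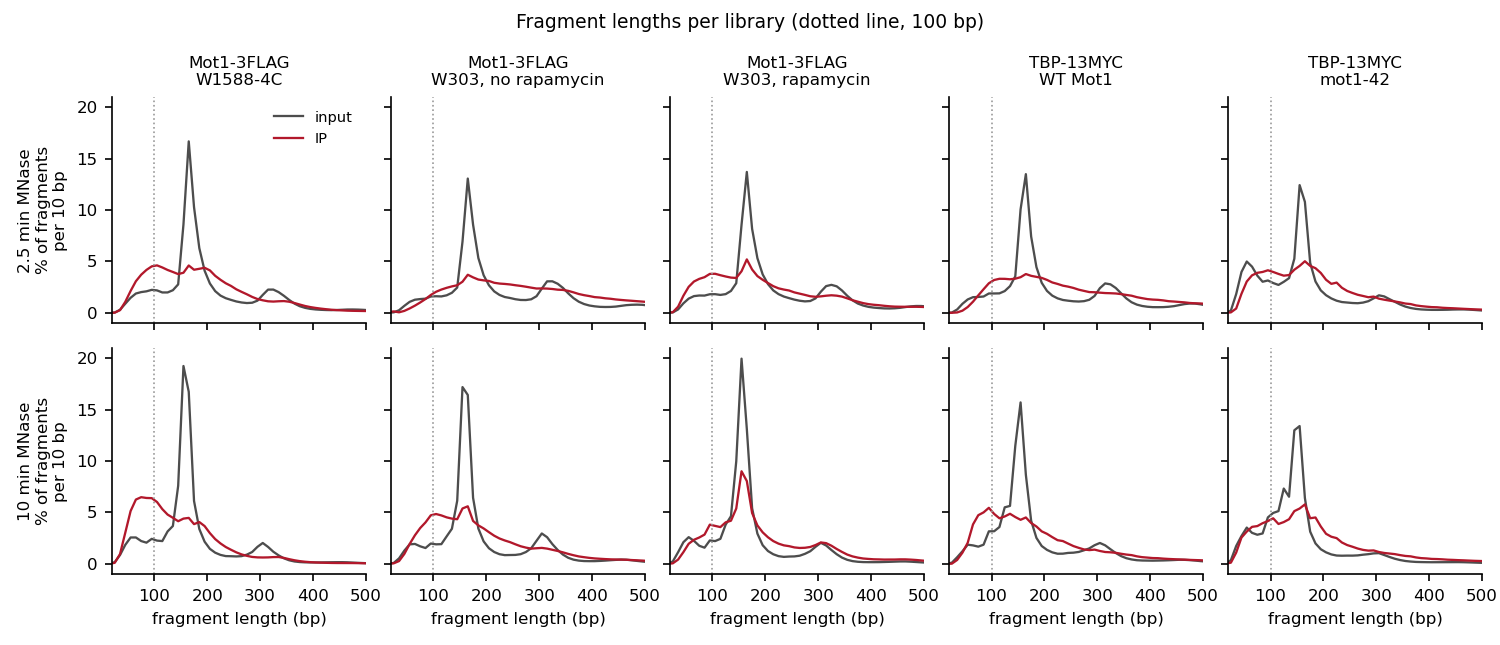
Share of yeast fragments (%) per 10 bp of fragment length (bp) in each of the 20 libraries, input in grey and IP in red, with 2.5 min MNase in the upper panels and 10 min in the lower. Inputs peak at the nucleosome length, and fragments at or below 100 bp (dotted line) were more frequent in the Mot1 IP of W1588-4C at 10 min than in its input (35.4% against 14.9%) but less frequent in the Mot1 IP of W303 without rapamycin at 2.5 min (5.89% against 7.81%).

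The first comparison asked where Mot1 and TBP sat in cells with functional Mot1. The strongest Mot1 promoters belonged to genes of several functions. The window shared by ATP7, a subunit of the mitochondrial ATP synthase, and PUT3, the activator of proline use (R64/sacCer3, chromosome XI, 407990 to 408289), had a Mot1 log2 IP over input of 1.80 at 2.5 min and 1.76 at 10 min. AFG3, a protease of the mitochondrial inner membrane (chromosome V, 191789 to 192088), had 1.82 and 1.73, and the window shared by the TOR complex subunit LST8 and the cochaperone SIS1 (chromosome XIV, 619767 to 620066) had 1.53 and 1.96. Next by the same ranking came VID24, GPD1 (glycerol synthesis), RAS2 (a GTPase that signals nutrient state), LCB1 (sphingolipid synthesis), YAP1802, VHR1, PNC1 (a nicotinamidase), and the citric acid cycle enzymes IDH1 and CIT1, the last with 1.32 and 1.25.

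Of 5579 promoters, 81 were Mot1-bound, that is at least 2-fold above input at both times (1.45%, 1.15 to 1.80%). None of the 456 windows between convergent genes, used as background, met the rule, which allows a share of up to 0.806%. The TBP rule was met at 1604 promoters in WT Mot1 cells (28.8%, 27.6 to 29.96%) and at 6 background windows. Mot1 and TBP shared promoters: 72 of the 81 Mot1-bound promoters were TBP-bound (88.9%, 80.0 to 94.8%), where independent sets would share 23.3. Across promoters, Mot1 and TBP log2 values had a Spearman rho of 0.36 at 2.5 min and 0.62 at 10 min (promoters are not independent replicates), although the proteins were measured in different strains and only the TBP cells had been shifted to 35 °C. The number of Mot1-bound promoters depended strongly on the threshold and on the fragments counted: it was 493 at 1.5-fold, 2 at 3-fold, 32 with repeats of a fragment counted once and 1092 with fragments of all lengths. With 1 digestion time alone it was 143 (2.5 min) or 191 (10 min).

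TBP was strongest upstream of TIM21, a subunit of the mitochondrial protein import machinery (chromosome VII, 554968 to 555267), with a log2 IP over input of 3.92 at 2.5 min and 4.72 at 10 min. It was followed by DSC3, the hyperosmotic response gene HOR7, the mitochondrial ribosomal protein gene RML2, URA8 (CTP synthase, 3.16 and 3.63), the cell wall protein gene HSP150 (3.12 and 3.36) and TIF2 (translation initiation factor eIF4A, 3.06 and 3.46). The window shared by LSC1 and ARP8 had 3.00 and 3.85, and UFO1 2.99 and 4.02. APE3, a vacuolar aminopeptidase, IDH1 (2.96 and 3.34) and YDJ1, an Hsp40 cochaperone (2.94 and 3.18), completed the leading 12. The promoter of the TBP gene SPT15, shared with SCC4, had a TBP value of 2.96 and 2.63 and a Mot1 value of 0.54 and 0.63. With a window of 200 bp the mean TBP value there turned from 2.79 to -0.21.

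Gene groups differed in Mot1 log2 IP over input relative to random promoter lists of the same size and similar IP density. Such lists share the numerator of the ratio, so the percentiles mainly reflect the input and do not rank the amount of Mot1. The median Mot1 log2 IP over input was 0.16 over all promoters, 0.74 at 20 promoters of glycolysis and fermentation (percentile 99.4 among 10000 random lists), and 0.58 at 35 of oxidative phosphorylation (percentile 100). It was 0.58 at 25 of heat shock proteins and chaperones (percentile 99.9), 0.53 at 31 of the general stress response (percentile 100) and 0.46 at 136 of cytosolic ribosomal proteins (percentile 100). Mot1-bound examples were PGK1 (1.22 at 2.5 min and 1.69 at 10 min), GPM1 and TDH2 of glycolysis, ATP7, ATP4 and COX13 of oxidative phosphorylation, GPD1, PNC1, TPS2 and TPS1 of the stress response, and RPL27B, RPL41B and RPS23B among ribosomal protein genes. At 83 promoters of ribosome biogenesis the Mot1 median was -0.20 and lay under all random lists (percentile 0), and none was Mot1-bound. Histone promoters (10, median 0.59, percentile 96.6), the 3 promoters linked to Mot1 in the literature (0.67, percentile 97.8), phosphate (15, 0.31, percentile 89.2), proteasome (31, 0.49, percentile 83.8) and galactose genes (8, 0.10, percentile 83.6) lay high among the random lists. Lower lay amino acid biosynthesis (53, 0.25, percentile 59.5), hexose transporters (16, -0.15, percentile 52.0), seripauperins (30, -0.37, percentile 40.7), the COS family (12, -0.05, percentile 35.9), mitochondrial ribosomal proteins (63, 0.20, percentile 13.5) and mating genes (23, -0.05, percentile 4.65).

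TBP had a different order. Glycolysis led with a median log2 IP over input of 2.30 (percentile 99.4), 17 of its 20 promoters bound, PGK1 at 2.71 and 3.52, ADH1 at 2.59 and 3.27 and TPI1 at 2.51 and 3.06. Promoters of the subtelomeric COS family followed at 1.86 (percentile 99.96, 9 of 12 bound), histone genes at 1.86 (percentile 62.3, 9 of 10), proteasome genes at 1.66 (percentile 36.1, 24 of 31) and general stress genes at 1.24 (percentile 98.9, 15 of 31). Cytosolic ribosomal protein promoters had a median of 1.19 with 73 of 136 bound, above the median of 0.74 over all promoters. They lay below the random lists of like IP density (percentile 0), as did ribosome biogenesis at 0.54 with 12 of 83 bound (percentile 0). As for Mot1, these percentiles mainly reflect the input and do not show low TBP. None of the 30 seripauperin promoters was bound (median -1.42), and hexose transporters had a median of -1.12, with HXT3, HXT2 and HXT1 bound. Medians between these were found for heat shock proteins (1.22, percentile 60.5, 13 of 25 bound), oxidative phosphorylation (1.21, percentile 46.5, 18 of 35), amino acid biosynthesis (1.07, percentile 12.9, 25 of 53), mitochondrial ribosomal proteins (1.03, percentile 35.2, 21 of 63), phosphate (0.92, percentile 64.7, 7 of 15), mating (0.71, percentile 83.1, 6 of 23) and the literature promoters (0.61, with URA1 bound). By contrast, galactose genes had -0.08 and 0 of 8 bound.

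At the 72 promoters bound by both proteins, the Mot1 summit lay upstream of the TBP summit at 44 (61.1%, 48.9 to 72.4%) and downstream at 24. Of the pairs 38 lay within 20 bp, against 5 to 17 in the central 95% of shuffles of the pairs among these promoters. The Mot1 IP summit also lay within 20 bp of the summit of its own input at 39 of the 72, and that input within 20 bp of TBP at 26. The median distance was 17.5 bp between the Mot1 and TBP IP summits, 15 bp between Mot1 IP and its input, 64 bp between Mot1 input and TBP IP, and 78.5 bp between TBP IP and its input (22 within 20 bp). The 2 inputs lay closer to each other than the 2 IPs did, at a median of 9.5 bp with 42 within 20 bp. The median offset was 5.5 bp upstream (0 to 10), with median summits 185 bp (Mot1) and 151 bp (TBP) upstream of the start codon. Fragments of 75 bp or less gave 21.5 bp upstream.

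**Figure D2:**
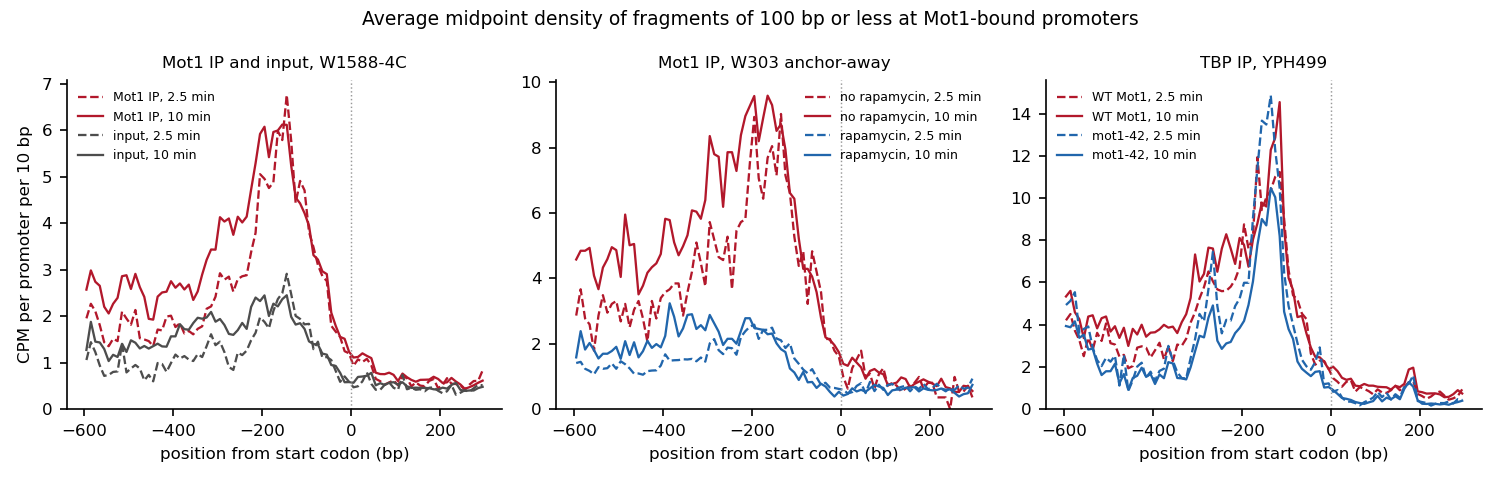
Mean fragment density (CPM per promoter and 10 bp) against position from the start codon (bp) over the 81 Mot1-bound promoters, for Mot1 IP and input in W1588-4C (left), Mot1 IP in W303 with and without rapamycin (middle) and TBP IP in YPH499 (right), dashed at 2.5 min and solid at 10 min. In W1588-4C the IP reached 6.76 at 2.5 min against 2.91 in the input. In W303 at 10 min the maximum was 9.59 at -165 bp without rapamycin. With rapamycin it was 3.24 at -385 bp, another place, where the input with rapamycin also had its maximum (2.23).

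The next comparison asked how TBP differed between cells with the temperature-sensitive mot1-42 allele and WT cells, both heat shocked. The libraries also differed in mitochondrial fragments (0.690% to 1.06% in mot1-42, 0.00139% to 0.00349% in WT), which cannot be told apart from the allele. The clearest pattern separated stress and chaperone genes from ribosomal protein genes. TBP was higher in mot1-42 at HSP12, a small heat shock protein whose window overlaps that of YFL015C (chromosome VI, 106964 to 107263 for YFL015C), with log2 mot1-42 over WT of 2.31 (1.65 to 3.14) at 2.5 min and 2.70 (2.32 to 3.26) at 10 min for HSP12. It was lower at RPL31B, a protein of the large ribosomal subunit (chromosome XII, 931756 to 932055), with -3.23 (-3.83 to -2.78) and -3.73 (-4.27 to -3.40). Among the 2523 promoters TBP-bound in either strain, 131 had higher TBP in mot1-42 (5.19%, 4.36 to 6.13%) and 204 lower (8.09%, 7.05 to 9.22%). Background windows met the same rule at 4.61% higher (2.87 to 6.95%, 21 of 456) and 4.82% lower (3.05 to 7.21%, 22 of 456). The share of higher promoters in the bound set was about that of the background, but these windows were not selected for TBP. Over all 5579 promoters, likewise not selected, 165 were higher and 850 lower, with a median of -0.24 (-0.28 to -0.21).

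General stress genes, which respond to many stresses, had the highest group values with the heat shock list. Of 26 bound general stress promoters 11 were higher and 1 lower, with a median of 1.17 (0.68 to 1.54, percentile 100), among them HSP12, TFS1 (a carboxypeptidase Y inhibitor, 2.19 and 1.93) and FMP45 (1.92 and 2.31). The 1 lower member was PNC1 (-1.89 and -1.65), which is itself Mot1-bound. Of 21 bound heat shock and chaperone promoters 7 were higher and 0 lower, with a median of 1.18 (0.20 to 1.38, percentile 100), including the mitochondrial Hsp70 gene SSC1 (2.34 and 1.72), HSP42 (1.88 and 1.61) and HSP82, the inducible Hsp90 (1.90 and 1.47). SSA1, a cytosolic Hsp70, had 2.60 at 2.5 min but 0.86 at 10 min and so missed the rule. COS family promoters (11 bound) had a median of 0.87 (0.31 to 1.11, percentile 99.3), 2 of them higher, COS8 (1.07 and 1.17) and COS5 (1.08 and 1.13). These 3 medians kept their sign under each scaling tried, but input division also raised the median over all 2523 promoters from 0.15 to 0.69. Against that, general stress had 1.20 and heat shock 1.05 when input-divided. In WT 15 general stress, 13 heat shock and 9 COS promoters were bound. The others entered through mot1-42 alone, a choice that favours higher values. Over all members, bound or not, the medians were 1.07 in general stress (31, percentile 100), 0.81 in heat shock (25, percentile 99.99) and 0.83 in the COS family (12, percentile 99.2).

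Cytosolic ribosomal protein promoters gave the lowest group value. Of 75 bound members 34 were lower and 1 higher, with a median of -1.02 (-1.46 to -0.64, percentile 0), which stayed negative under each scaling (-0.56 when each IP ratio was divided by the input ratio). Besides RPL31B the lower members included RPL15B (-2.99 and -3.49), RPP1B (-3.35 and -2.86), RPS18A (-3.12 and -3.01) and the window shared by RPS10A and YOR292C (chromosome XV, 866798 to 867097, -3.07 and -3.39). The 1 higher member was RPL4A (2.084 and 1.886). Proteasome promoters (26 bound, 0 higher and 5 lower) had a median of -0.17 (-0.75 to -0.03, percentile 0.4), with RPT1 at -2.25 and -1.40 and PUP2 at -1.81 and -1.39, but the sign turned with the input-divided ratio (0.37). Glycolysis promoters (17 bound) had a median of -0.16 (-0.69 to 0.21, percentile 0.13), which also turned positive (0.56) with the input-divided ratio. Under that setting the median over all 2523 promoters was 0.69, above both the proteasome and the glycolysis median. The glycolysis median was 0.12 at 2.5 min and -0.42 at 10 min, and no member met the rule, with ADH1 at -0.61 and -1.84 and HXK1 at 1.78 and 0.71.

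**Figure D3:**
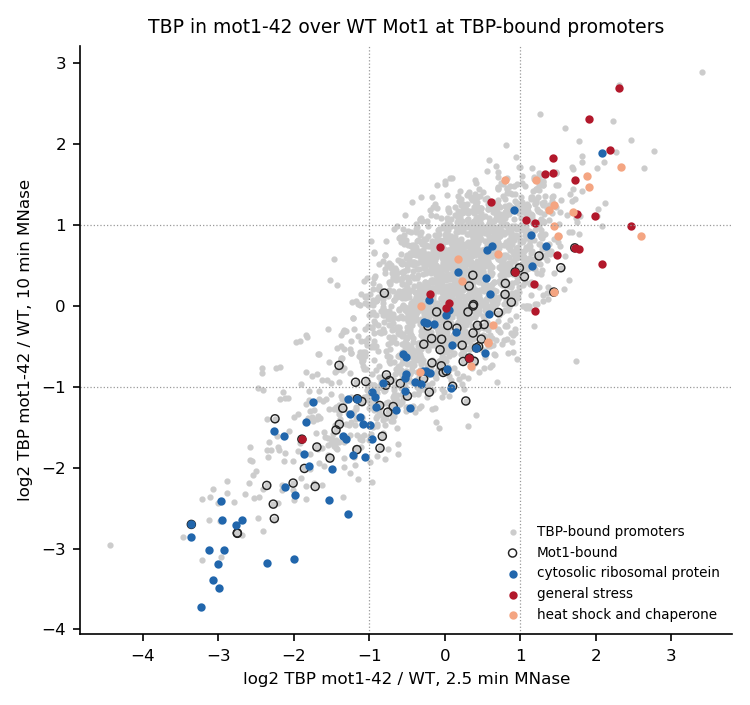
Log2 TBP in mot1-42 over WT at 2.5 min (horizontal) and 10 min (vertical) MNase for the 2523 TBP-bound promoters, each point 1 promoter, with dotted lines at the 2-fold limits. Ribosomal protein promoters (blue) reach -3.73 at 10 min, while general stress (red) and heat shock (orange) promoters lie mostly above 0, and Mot1-bound promoters (open circles) extend to the lower left.

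Other leading promoters belonged to no fixed list. Higher were BIO3 and BIO4 of biotin synthesis, which share a window (chromosome XIV, 733991 to 734290, 2.23 and 2.29), the meiotic genes RIM4 (2.46 and 2.05) and DMC1 (1.82 and 1.86), RGI1 (respiratory growth, 2.78 and 1.92), the RNA helicase gene DED1 (2.27 and 1.90), PCD1 (1.82 and 1.79) and YLR177W (2.11 and 1.78). Lower were YGR161W-C (-3.21 and -3.14), the exocytic t-SNARE gene SSO1 (-2.96 and -3.10), YPT6, a Rab GTPase of the Golgi (-4.43 and -2.95), THO1 (-3.47 and -2.85) and YIL055C (-2.75 and -2.81), besides RPL13B and RPL12A. The largest value, at MOT1 itself (chromosome XVI, 404084 to 404383, 3.41 and 2.89), involved a gene carried on the plasmid: its input was higher in mot1-42 by a log2 of 1.89, and the input-divided values were 1.81 and 0.72. Of the 3 promoters linked to Mot1 in the literature, URA1 (pyrimidine synthesis) was bound and had 0.38 and 0.07, INO1 (inositol synthesis) 1.39 and 0.25, and BNA1 (NAD synthesis) -3.38 and -3.80, the last 2 not TBP-bound in either strain. The SPT15 promoter had 0.60 and 1.00, and a mean of -0.89 with a window of 200 bp.

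The remaining lists had medians between -0.22 and 0.23. Ribosome biogenesis (40 bound, 2 higher, 0 lower) had 0.23 (0.07 to 0.45, percentile 90.9), with DBP2 at 1.29 and 1.04 and SAS10 at 1.16 and 1.12 as its higher members. Amino acid biosynthesis (32 bound, 4 higher and 3 lower) had 0.05 (-0.41 to 0.65), with ARG4 higher (1.21 and 1.45) and MET3 (-2.21 and -1.74), ASN2 and SER33 lower, and turned to -0.08 when scaled to background windows. Oxidative phosphorylation (24 bound, 4 higher, 2 lower) had -0.01 (-0.45 to 0.68, 0.43 input-divided and 0.02 without ribosomal DNA), with RIP1 (1.19 and 1.57) and QCR2 higher and ATP4 (-2.01 and -2.19) and ATP7 (-1.35 and -1.26) lower. Mitochondrial ribosomal proteins (33 bound, 0 higher, 2 lower) had -0.11 (-0.43 to 0.31, and 0.61 input-divided), with MRP20 (-1.31 and -1.46) and RSM22 lower. Small lists held 1 lower promoter each in hexose transporters (5 bound, median -0.22, HXT1 at -1.47 and -1.73), phosphate (7 bound, -0.19, PHM8 at -1.10 and -1.18) and histones (9 bound, -0.20, HTA1 at -1.26 and -2.07), and 2 in mating genes (9 bound, -0.15, PRM8 and PRM4). These 4 medians were positive when input-divided (0.86, 0.26, 0.41 and 0.30). Galactose genes had 1 bound promoter, GAL80 (1.06 and 0.42), and seripauperins 0. Over all members, bound or not, the median was 0.74 in hexose transporters (16, percentile 99.8) and 0.87 in seripauperins (30, percentile 100). In galactose genes it was -0.19 (8, percentile 69.1). Ribosome biogenesis had -0.24 over all 83 members (percentile 72.6) and amino acid biosynthesis -0.27 over all 53 (percentile 9.75). Both were opposite in sign to the medians over bound members, and near the -0.24 over all coding promoters. Only 12 ribosome biogenesis promoters were bound in WT, so most of the 40 entered through mot1-42 alone.

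**Figure D4:**
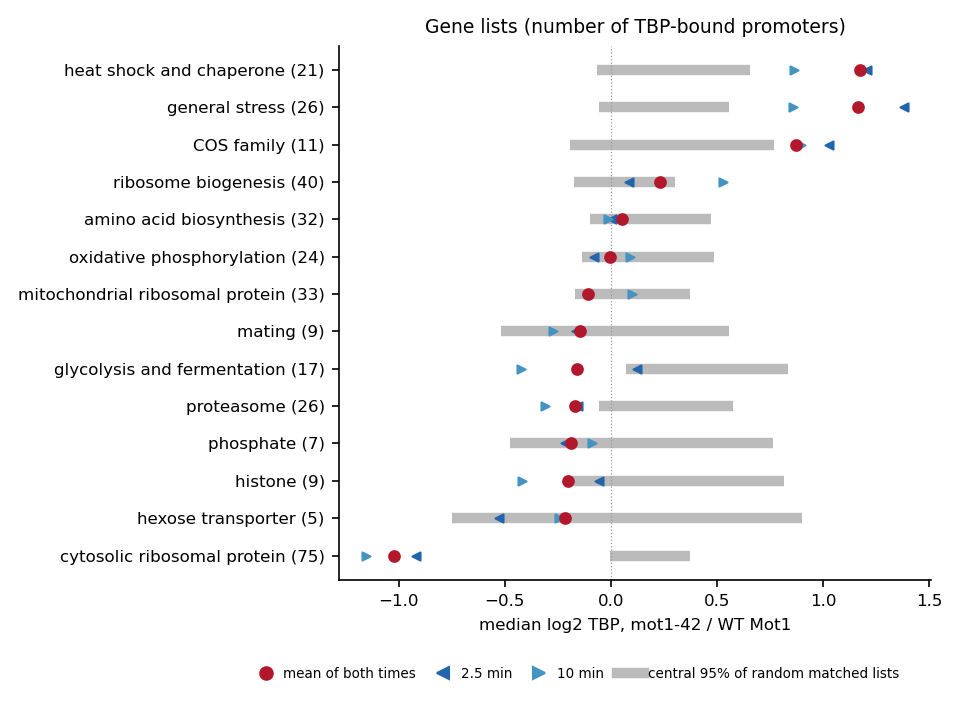
Median log2 TBP in mot1-42 over WT for each fixed gene list, over its TBP-bound promoters (number in parentheses), as the mean of both digestion times (circle), at 2.5 min (left triangle) and at 10 min (right triangle). Grey bars span the central 95% of random matched lists, which general stress (1.17), heat shock (1.18) and the COS family (0.87) exceed and cytosolic ribosomal proteins (-1.02), glycolysis (-0.16) and proteasome (-0.17) lie below. Glycolysis, proteasome, histone, hexose transporter, phosphate, mating, mitochondrial ribosomal protein and oxidative phosphorylation medians change sign when the ratio is divided by the input ratio. That division also moves the median over all 2523 promoters from 0.15 to 0.69. The amino acid biosynthesis median changes sign when scaled to background windows.

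Promoters Mot1-bound in W1588-4C lay lower than other TBP-bound promoters in the comparison of mot1-42 with WT, more so at 10 min. Of the 75 promoters both Mot1-bound and TBP-bound in either strain, 0 were higher (up to 4.7995%) and 19 lower (25.3%, 15.99 to 36.7%), among them PNC1, ATP7, ATP4, RPT1, PHM8, RPL27B, RPS23B and MDM35. Their median was -0.42 (-0.83 to -0.22, percentile 0). Over all 81 it was -0.22 at 2.5 min and -0.74 at 10 min. Median TBP IP over input there was 1.84 in both strains at 2.5 min, but 2.32 in WT and 1.82 in mot1-42 at 10 min. Median Mot1 log2 IP over input at 10 min was 0.69 at the promoters with lower TBP, 0.35 at those with neither call and 0.17 at those with higher TBP. All 204 promoters with lower TBP were bound in WT, against 62 of the 131 with higher TBP. The choice of promoters bound in either strain largely fixes this contrast, since those with higher TBP can enter through mot1-42 alone.

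The balance of higher and lower promoters depended on scaling, which the design does not fix, and on the fragments counted and required. The minimum in the bound rule is a raw count, and the libraries differed in depth. At 2.5 min the WT IP held 581105 nuclear fragments of 100 bp or less, against 2683437 in mot1-42. A promoter of like CPM thus met the minimum more easily in mot1-42. The share of higher among the promoters past the rule was 39.1%, but 83.0% (526 higher, 108 lower) when each IP ratio was divided by the input ratio, 24.9% (75 and 226) when scaled to background windows, 25.1% (124 and 371) with all fragment lengths, 49.5% (140 and 143) with fragments of 75 bp or less, and 64.2% (131 and 73) with at least 100 fragments required. The median over all 2523 promoters was 0.15, and shifted to 0.69 with the input-divided ratio and to 0.02 with background scaling, so group values are to be read against it: at the 81 Mot1-bound promoters the medians under the same settings were -0.44, -0.13 and -0.57. The value of 0.15 holds for the set chosen as bound: over all 5579 promoters the main median was -0.24. Inputs alone gave 1 higher and 15 lower promoters, but their median log2 ratio at the 2523 promoters was -0.54. Fragments of 100 bp or less made up 25.6% (2.5 min) and 22.1% (10 min) of the mot1-42 inputs against 9.26% and 12.6% of the WT inputs.

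The last comparison asked whether Mot1 stays on promoters when TBP is removed from the nucleus, in the W303 strain with against without rapamycin. Mot1 was lower after rapamycin at most promoters it bound in W1588-4C. However, the IPs without rapamycin held FPR1, which the W303 strain lacks, at 1.21 (10 min) and 2.07 (2.5 min) of the average density. DNA of another strain in them is not excluded, and all rapamycin ratios rest on these libraries. RHO1, the GTPase that controls cell wall synthesis (chromosome XVI, 875068 to 875367), had log2 rapamycin over none of -3.57 (-4.50 to -2.81) at 2.5 min and -3.50 (-4.26 to -3.01) at 10 min. The glycolytic gene PGK1 (chromosome III, 137446 to 137745) had -2.64 (-3.20 to -2.12) and -2.55 (-2.84 to -2.30), and GPD1 (chromosome IV, 411525 to 411824) had -2.40 (-3.17 to -1.66) and -2.62 (-3.02 to -2.30).

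Of the 81 Mot1-bound promoters, a set chosen in the other strain, 65 were lower (80.2%, 69.9 to 88.3%), 0 were higher (up to 4.45%) and 79 were below 0 at both times. Their median was -1.77 (-1.93 to -1.65), with -1.64 at 2.5 min and -1.96 at 10 min, against -0.45 and 0.12 in background windows, of which 12 of 456 were lower. Gene bodies had a median of 0.71 (0.45 at 2.5 min and 0.82 at 10 min), opposite in sign, and how much of the promoter value is owed to scaling was not settled. Inputs at the same promoters had medians of -0.14 and -0.24 and none was lower by the rule. Median Mot1 IP over input there went from 1.72 (2.5 min) and 2.00 (10 min) without rapamycin to 0.20 and 0.32 with it. The next promoters were the ABC transporter gene ADP1 (-2.57 and -2.79), BUD7, AUA1, the heme lyase gene CYC3, the mitochondrial protein gene MDM35 (-2.39 and -2.82), the tropomyosin gene TPM1 (-2.30 and -2.36), PNC1, the elongation factor gene EFB1 (-2.43 and -2.29) and the window shared by TPS1 (trehalose synthesis) and MEO1 (-2.27 and -2.42). The 2 promoters not below 0 at both times were YOR302W (0.25 and -0.70) and CMR3 (0.22 and -0.20), named after their values were seen.

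**Figure D5:**
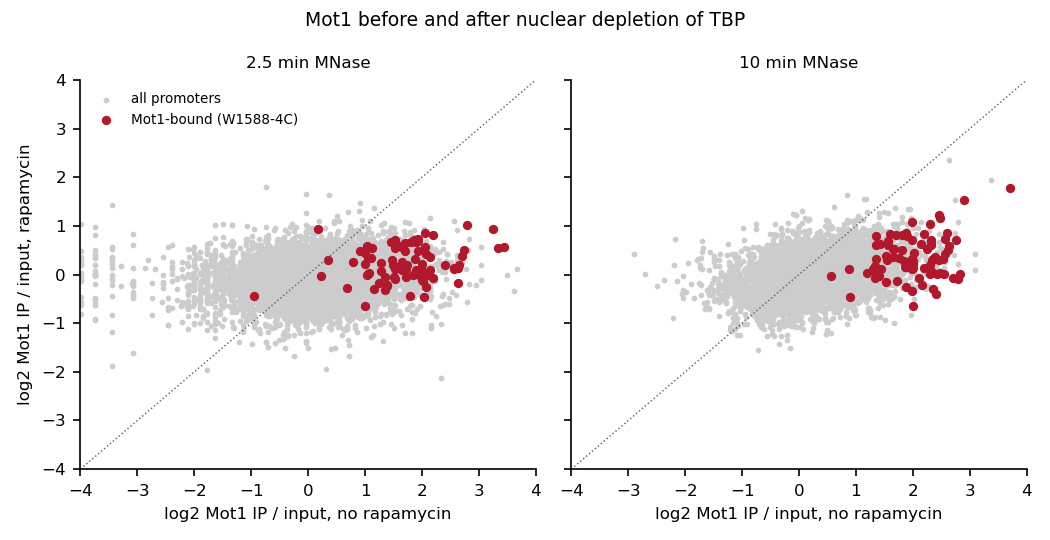
Log2 Mot1 IP over input in W303 with rapamycin (vertical) against without rapamycin (horizontal), at 2.5 min (left) and 10 min (right) MNase, for all promoters (grey) and the 81 that were Mot1-bound in W1588-4C (red). The red points lie to the right and mostly below the diagonal, with medians of 1.72 and 2.00 without and 0.20 and 0.32 with rapamycin.

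By group, general stress promoters had a median Mot1 log2 rapamycin over none of -1.13 (percentile 0) with all 4 of the Mot1-bound members lower, GPD1, PNC1, TPS2 (-1.78 and -2.93) and TPS1. Glycolysis had -1.36 (percentile 0.04), with PGK1 and TDH2 (-1.39 and -2.53) lower and GPM1 at -0.57 and -1.97. Oxidative phosphorylation had -1.18 (percentile 1.43), with ATP7 (-2.38 and -2.09) and ATP4 lower, and histone promoters had -1.16 (percentile 5.73) and proteasome promoters -1.11 (percentile 6.14) with RPT1 lower. Cytosolic ribosomal proteins (-0.76, percentile 79.2, with RPS23B, RPL41B and RPL27B lower) and heat shock proteins (-0.65, percentile 84.7, with YDJ1 lower) were below 0 but above most random lists. Mitochondrial ribosomal proteins (-0.59, percentile 59.6), phosphate (-0.51, percentile 51.7, with PHM8 lower), the COS family (-0.47, percentile 20.8) and the 3 literature promoters (-0.67, percentile 34.1) lay among them, and all 6 medians stayed below 0 under each scaling. Ribosome biogenesis had the highest place among random lists, with -0.05 (percentile 100), and was above 0 under the other scalings (0.13 input-divided, 0.35 to background). Amino acid biosynthesis had -0.38 (percentile 98.6, 0.02 scaled to background, LYS4 and ADE3 lower) and mating -0.03 (percentile 97.6, 0.37 scaled to background). In hexose transporters it was -0.12 (percentile 46.9, 0.27 scaled to background), in galactose genes -0.22 (percentile 37.5, 0.17 scaled to background and 0.12 input-divided) and in seripauperins 0.41 (percentile 67.7). Over all 5579 promoters the median was -0.42, and -0.27 input-divided and -0.03 with background scaling, and at the 81 promoters it was -1.53 and -1.38 under these. The difference from all promoters thus held its sign when input-divided. Background scaling moves all promoters nearly alike and could not change it. The count of 65 was 24 with fragments of 75 bp or less and 23 with repeats counted once, when 50 and 32 promoters were Mot1-bound. It was 44 of the same 81 when scaled to background windows and 56 of them when input-divided. With a pseudocount of 5 CPM it was 51, over Mot1-bound promoters selected again with that pseudocount.

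At tRNA genes, transcribed by RNA polymerase III, TBP was high while Mot1 was low and differed between the strains. The 275 tRNA genes had a median TBP log2 IP over input of 3.65 (3.57 to 3.73) in WT and 4.399 (4.32 to 4.48) in mot1-42, with 98.6% and 98.2% at least 2-fold above input at both times, whereas Mot1 in W1588-4C had -0.18 (-0.24 to -0.13) and reached 2-fold at 0%. In W303 without rapamycin the Mot1 median there was 0.41 (0.32 to 0.45), above coding promoters (0.23) and background windows (-0.21). The share at least 2-fold above input at both times was 4.73% against 10.2% of coding promoters, both without a minimum of IP fragments. With the minimum of the bound rule, 207 of 5579 coding promoters passed, and the tRNA share under it is not given. These shares therefore do not rank tRNA genes against coding promoters. In W303, 17 of the 275 tRNA genes were lower after rapamycin, against 599 of 5579 coding promoters. TBP in mot1-42 over WT was 0.47 at tRNA genes (0.41 to 0.54), with 6 higher and 0 lower. By the same rule 165 of the 5579 coding promoters were higher and 850 lower, and 21 and 22 of the 456 convergent intergenic windows. The 75 snoRNA genes had 0.29 (-0.18 to 0.66) for TBP in WT and -0.23 (-0.54 to -0.05) for mot1-42 over WT, with 0 higher and 7 lower. Coding promoters had a median of -0.24 for the latter, so the snoRNA value does not set this class apart. The 5 snRNA genes had 1.95 and the 11 other RNA polymerase III genes 2.22 for TBP in WT. For comparison, gene bodies had -2.34 (2240 windows) and convergent intergenic windows -1.25.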

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

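The tests on the fly fragments, on whether mitochondrial fragments had been left out and on the mitochondrial DNA state of the strains were chosen after the results were seen. The predictions of the other tests were written before the values of those tests were seen, but the patterns, the retrograde list and the alternatives for list medians were chosen after the data had been examined. A first test of sharing between the fly libraries was replaced once its result was seen, because it depended on fragment length and depth. Each group had 1 library, so no pattern was set against replicate spread.

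Fragments assigned to Drosophila melanogaster, which enter no comparison, made up 47.95% of the Mot1 IP without rapamycin at 10 min, 72.59% of that IP at 2.5 min, 27.28% of the input at 10 min and 70.41% of the input at 2.5 min. Reading the same amplified fly library in both libraries of a pair would leave many identical fragments in both, but at most 0.2023% of distinct fly fragments were found in the other library of any pair, against 5.97% or more repeats within a library. Fly chromatin digested together with the yeast would be shortened with it, yet the median fly length differed between digestion times by at most 7.692% as much as the yeast length (4 bp against 88 bp in the IP, 2 bp against 26 bp in the input). A fly sample prepared apart and read on the same run remains open and was not tested, and the labels list Drosophila melanogaster beside yeast without saying how it was added. The fly share lowers the depth of the yeast fragments, with 138079 nuclear fragments of 100 bp or less in the IP at 2.5 min, and no biological explanation was tested.

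The ribosomal protein and general stress promoters parted in mot1-42, with a gap of 2.19 log2 between their medians. Unequal digestion, as far as the inputs measure it, does not account for the whole gap, which was 1.765 after division by the input ratio. Whether fragments in the TBP IP respond to MNase as the input does was not tested, so a further effect of digestion stays open. Repeats were more frequent in the mot1-42 IPs (57.5% at 10 min and 61.8% at 2.5 min against 38.8% and 21.7% in WT). They do not account for the whole gap either, since it was 1.702 with repeats counted once. The mitochondrial DNA state of the strains cannot be told apart from the mot1-42 allele, because 0 library pairs differed in MOT1 without differing in mitochondrial DNA. Loss of Mot1 function during the heat shock, as the design names it, stays open and untested beside this, as does any other difference between the cultures.

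In the WT Mot1 libraries mitochondrial fragments were nearly missing, with 0.00139% to 0.00349% of fragments against 0.690% to 1.06% in mot1-42. Removal of all these fragments when the files were made would leave 0, whereas each of the 4 WT libraries listed at least 171, spread over 68 to 79 of the 86 mitochondrial bins of 1 kb, but a filter that left some was not tested and stays open. A WT culture without mitochondrial DNA may account for it, and such cells induce the retrograde response, but the median of 7 bound retrograde promoters lay at percentile 13.52 of random lists, between the limits set for and against, so this stays open. The members moved apart, with CIT2 at -1.33 and DLD3 at 1.29.

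Mitochondrial fragments were also a larger share of the Mot1 IP than of its input in W303, at 2.498% with rapamycin at 10 min against 0.587%, 0.9184% without rapamycin at 10 min against 0.349%, 1.483% with rapamycin at 2.5 min against 0.553%, and 0.9281% without rapamycin at 2.5 min against 0.328%. The direction was the same in the other strains, but smaller in size. The ratio of IP to input share was 2.63 to 4.26 in W303, 1.005 (2.5 min) and 1.496 (10 min) in W1588-4C, and 1.05 to 1.91 for TBP in YPH499.

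Background windows had a median log2 TBP in mot1-42 over WT of -0.07756 at 2.5 min and 0.4743 at 10 min, opposite in sign, and the difference between the times was not tested.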

How the results depend on the processing

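Scaling without the ribosomal DNA and the alternatives for list medians were chosen after the data were seen. No paired test was made, because each group had 1 library and digestion times are not replicates. Of 2038 values for 212 results of named promoters 27 had another sign than the main value, 1 of them at a promoter that met the rule, and of 280 values for 35 list medians 56 had, 2 of them where the main interval excluded 0. The 4 TATA box results and their 60 alternatives, of 180 fixed before the data were examined, were not run, for want of a genome sequence. For the values below, other than those whose change follows from a looser or stricter threshold, from fewer promoters or from requiring 1 time in place of both, the cause was not tested.

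Each setting except input division and background scaling selected its own bound promoters again, so the other medians below are over other sets than the main 81. Counts are given as Mot1-bound, TBP-bound, bound by both, higher TBP, lower TBP and lower Mot1, with main values of 81, 1604, 72, 131, 204 and 65. At 1.5-fold they were 493, 2584, 420, 421, 672 and 265, and at 3-fold 2, 596, 2, 17, 21 and 1. With 10 min MNase only, Mot1-bound was 191, both 175, higher TBP 335, lower TBP 555 and lower Mot1 166. With 2.5 min MNase only, Mot1-bound was 143, both 113, higher TBP 280 and lower TBP 411, and the median Mot1 change was -1.339 (main -1.773). A window 200 bp upstream gave a median of -1.65. A window from 400 bp upstream to 100 bp downstream gave Mot1-bound 46, both 39, lower Mot1 33 and a median of -1.644. With 75 bp or less, Mot1-bound was 50, both 32, lower Mot1 24, the median -1.519 and the Mot1 offset 21.5 bp (main 5.5). With all lengths, Mot1-bound was 1092, both 964, lower TBP 371, lower Mot1 569, higher Mot1 2 (main 0) and the median -1.278. With fragments of the same start and end counted once, Mot1-bound was 32, both 29, higher TBP 73, lower TBP 131 and lower Mot1 23. A minimum of 100 fragments gave TBP-bound 668, both 46 and lower TBP 73. Promoters not shared with a divergent gene gave TBP-bound 1030 and higher TBP 86. The IP ratio divided by the input ratio gave higher TBP 526, lower TBP 108 and a median of -1.526. Scaling to background windows gave higher TBP 75 and a median of -1.375, and scaling without the ribosomal DNA a median of -1.63.

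Directions of called values turned in 3 cases: the TBP log2 IP over input at SPT15 was -0.2056 with a window 200 bp upstream, the proteasome median for mot1-42 over WT was 0.3673 with the input-divided ratio, and the amino acid biosynthesis median for rapamycin was 0.01557 with scaling to background windows. The last 2 went with shifts of the whole set. Input division moved the median over the 2523 promoters from 0.15 to 0.69, and background scaling that over all 5579 from -0.42 to -0.03. The median Mot1 change stayed negative under each alternative run, between -1.773 and -1.278 over the sets selected again. At the same 81 promoters it was -1.856 with all lengths, -1.962 with 10 min MNase only and -1.641 with 2.5 min MNase only. The smaller size with all lengths thus goes with the change of set. More Mot1-bound promoters were lower than higher after rapamycin under each.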

Other observations

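The tests of the gradient with Mot1, the subtelomeric group, the paralog comparison, the added lists and the comparison of the 2 Mot1 strains were chosen after the results were seen. Divided into 5 groups of 504 or 505 by Mot1 level at 10 min in W1588-4C, the 2523 TBP-bound promoters had median TBP changes in mot1-42 of 0.46 (0.41 to 0.54) at the lowest Mot1, then 0.28, 0.15 and -0.05, and -0.29 (-0.42 to -0.21) at the highest. Because that set is partly chosen on mot1-42, the same was run on promoters bound in WT (0.455 to -0.38, lowest to highest Mot1) and on all promoters (0.04 to -0.48). With groups formed within 20 strata of mean TBP density, the highest lay below the lowest by a log2 of 0.93 in the first set, 0.86 in the second and 0.95 in the third, outside the central 95% of 1000 shuffles (-0.16 to 0.13 in the set bound in WT). Promoters with higher TBP numbered 56, 26, 20, 15 and 14 in the same order, and those with lower TBP 5, 13, 30, 63 and 93. Promoters within 30 kb of a chromosome end, where the COS family lies, had a median of 0.41 (0.28 to 0.69, percentile 99.8, 87 bound), with 11 higher and 4 lower.

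Duplicated ribosomal protein genes had the same call for TBP in mot1-42 over WT in some pairs and not in others, with no test of the difference between copies. Of 21 pairs with both promoters bound, both copies were lower in mot1-42 in 7, such as RPL12A (-2.97) and RPL12B (-2.18) or RPL36A (-2.69) and RPL36B (-2.67), and 1 copy was lower in another 7. Examples of the latter were RPL31A (-0.46) and RPL31B (-3.48), RPP1A (-0.51) and RPP1B (-3.11), and RPS10A (-3.23) and RPS10B (-0.05). RPL4A (1.99) and RPL4B (-1.08) lay on opposite sides of 0. The B copy was below the A copy in 12 of the 21 pairs, and medians over bound copies were -0.85 (A, 32 promoters, 14 lower) and -1.27 (B, 33 promoters, 19 lower). Of the pleiotropic drug resistance list 3 promoters were bound (median -0.13), of which YOR1 was higher (1.28).

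In the W303 strain without rapamycin, 207 promoters were Mot1-bound, and 44 of them were among the 81 of W1588-4C, where independent sets would share 3.00 (3.005). However, the IPs without rapamycin held FPR1, which the W303 strain lacks. TRP1 was at 5.66 (2.5 min) and 7.29 (10 min) of the average density in them, against 1.37 and 2.03 in the Mot1 IPs of W1588-4C. They were thus not made up of W1588-4C DNA alone. A smaller share of such DNA is not excluded and would raise this overlap, so the overlap was not taken as agreement between independent strains. Of the 207, 167 were TBP-bound in WT cells and 181 had lower Mot1 after rapamycin, although this set was chosen on libraries that enter the ratio. With rapamycin 5 promoters were Mot1-bound.

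Marker genes matched the strain labels in the inputs, but FPR1 did not in all IPs. Relative to the genome, FPR1, which the W303 strain lacks, had 0.0425 to 0.178 of the average fragment density in W303 and 0.826 to 1.11 in the other strains, TRP1 had 2.14 to 2.33 in W303, and HIS3 had at most 0.00178 in YPH499. In the Mot1 IPs of W303, however, FPR1 had 1.21 (102 fragments, 10 min) and 2.07 (69 fragments, 2.5 min) without rapamycin, against 0.204 and 0.442 with rapamycin. It had 2.27 and 1.81 in the Mot1 IPs of W1588-4C, which has the gene. TRP1 had 7.29 (10 min) and 5.66 (2.5 min) in the W303 IPs without rapamycin, against 2.03 and 1.37 in those of W1588-4C. At 2.5 min both genes thus lay above W1588-4C, which a part of W1588-4C DNA would not give by itself. The source of the FPR1 fragments in the libraries without rapamycin was not tested. DNA of another strain in them is not excluded, and the rapamycin ratios rest on these libraries. MOT1, carried in YPH499 on a plasmid described as low copy (CEN ARS), had 1.48 (10 min) and 1.21 (2.5 min) in WT inputs but 10.5 and 8.47 in mot1-42 inputs, and LEU2, the plasmid marker, had 2.03 and 1.73 against 11.9 and 10.4. The raised region around MOT1 spanned chromosome XVI 398480 to 404479, with a median mot1-42 over WT ratio of 7.54, and at most 1.24 in the flanks. The number of plasmids per cell was not measured.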
